A study of Mus musculus with 51 samples.

How the data were processed

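Total RNA was taken with Trizol per the labels, which do not say how RNA was selected for the libraries. RNA was sequenced from mouse embryos at 18h, 20h, 22h and 24h, either control or knocked out (KO) for LoNA, a long noncoding RNA of the nucleolus. It was also sequenced from 2C-like mESC, mouse embryonic stem cells labelled as resembling the two-cell embryo, either control or knocked down (KD) for LoNA. Chromatin of 24h embryos was profiled with a tagmentation-based in-situ ChIP kit for H3K27me3, H3K4me3 and acetylated nucleophosmin (AcNPM1), the last also in LoNA KO embryos given an inhibitor of the acetyltransferase p300. The labels list 51 samples in 17 groups, of which 38 are RNA samples and 13 are ChIP samples. The series' own design text speaks of H3K27ac, while the sample labels and the deposited peak tables name H3K27me3 and H3K4me3, so those names are used.

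The deposited RNA tables hold raw read counts per gene, one table for each time and one for the mESC, with Ensembl gene IDs, biotypes and positions on the mouse build mm10. For these the authors' processing notes name Bowtie2 2.2.3, HISAT2 2.1.0 and HTSeq 0.6.0 without giving the role of each. Each deposited RNA table also carries a mean signal per gene over its libraries (baseMean, counts divided by size factors), which the authors computed. The authors' fold change, KO or KD over control, is given as a ratio in the 18h, 20h, 22h and mESC tables, and as a log2 value in the deposited 24h table. The deposited peak tables hold, for each called region, the read counts of both conditions, and the authors divided them by total reads to give RPM (reads in a peak scaled by the total). The total reads of each condition stand in the same deposited tables as a constant other quantity per column, and the authors' log2 ratio of both RPM columns is given for each peak. For the chromatin data the authors' notes name bcl2fastq 2.2, Bowtie2 2.1.0 and MACS2 2.1.1. The RPM and log2 columns were checked against the reads and totals, and the largest difference in RPM was 5e-05.

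The count tables have fewer columns than the labels have samples. At 18h, 20h and 22h each group has 3 columns against 4 labelled samples, and each mESC group has 2 columns against 3. Columns were assigned to groups by their prefix and table, and no column was tied to a labelled replicate number. At 24h each group has 4 columns, but within each group the columns formed pairs with a Pearson correlation of log2 CPM over 0.99, where CPM is counts scaled by library size. The columns of such a pair were summed, which left 2 libraries per group at 24h. The mESC columns of a group correlated at 0.998 and would be summed by the same rule, which would leave 1 library per group, so they were kept apart to allow a fit, and its p rests on the difference between columns this alike. The peak tables hold 1 column per condition also where the labels list 3 samples, so chromatin values have no replicates here. In the H3K27me3 and H3K4me3 tables the columns carry initials rather than group names, and they were read as control and KO from the direction of the table's ratio and the wording of its title. Whether the RNA replicates are separate pools of embryos or repeats of one preparation is not stated, so a p measures the spread between these libraries.

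The deposited mean of each gene was recomputed from its counts, with a tolerance of 0.02 on the log2 scale. All genes matched at 18h, 20h and 22h. At 24h the genes that did not match were these 4: Cdip1, Cdkn1a, Nupr1 and Mybbp1a. For mESC they were these 4: Cdkn1a, Zfp414, Zmat4 and Gm17382. For Mybbp1a at 24h the counts give a mean of 77.7 and the authors' deposited table gives 0.130, and for Gm17382 in mESC the counts give 191.1 and the authors' deposited table gives 0.257. These genes stayed in the fits with their counts as deposited, and their values are given with this limit.

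Counts were analysed with edgeR 4.0.16 in R 4.3.3, separately for each time and for the mESC, with TMM factors, filterByExpr, a quasi-likelihood fit and test, and Benjamini-Hochberg adjustment over the genes tested at a threshold of 0.05. CPM values use the TMM-scaled library sizes. Where 1 group had no counts, the fold is a lower bound from a floor of 3 counts over that group. Gene lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists of a comparison, for lists with at least 3 tested members. The 19 lists, fixed before the data were examined, are two-cell genes, Obox homeobox genes, maternal oocyte genes, ribosome biogenesis and nucleolus, cytosolic ribosomal proteins, PRC2 subunits, histone acetylation enzymes, pluripotency genes, developmental regulators that are PRC2 targets, major genome activation genes, p53 and stress response, cell cycle, markers of cumulus and granulosa cells, of trophectoderm and later embryo, of fibroblasts, of blood cells and of sperm and testis, mitochondrially encoded transcripts and replication-dependent histone genes. A further 3 lists, of autonomic neuron and chromaffin cell genes, of Y-linked genes and of primitive streak and gastrulation genes, were written after the data were seen. The named genes follow a rule also set before the data were examined. It takes up to 10 rises and 10 falls per comparison that passed the test without overlap of the groups at 10 CPM or more, leaving out predicted genes and pseudogenes, up to 4 members of each list by adjusted p, and Npm1, Ncl, Fbl, Ezh2, Ep300, Zscan4d, Zfp352 and Duxf3 in every case.

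The KO effect by time was tested in a joint edgeR fit of the 22 embryo libraries with a term for time, genotype and their interaction. Effects of different comparisons were set side by side by Spearman correlation of log2 changes across genes. An exact test over relabelled libraries was made on the same correlation of differences in mean log2 CPM. Peak lists were compared with bedtools 2.31.1 at an overlap of at least 1 bp against 1000 shuffles within chromosomes, for which the smallest p is 0.001. Genes were given promoter peaks when a peak lay within 2 kb of the start of 1 of 20021 protein-coding genes, from the positions in the RNA tables. The median log2 ratio of a list's promoter peaks was placed among those of 10000 sets drawn from all promoter peaks of the same table, matched in read depth. This percentile takes peaks as independent of each other and rests on 1 column per condition, so it is no test of the conditions. List membership of these genes was tested with Fisher's exact test, adjusted over all lists and peak tables. Intervals for log2 ratios of peaks and for shares are 95% Clopper-Pearson intervals, and intervals and floors cover counting error only. The remaining values were computed in Python 3.11.15.

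Both fits were tested on simulated data made from these tables, with 100 genes changed 4-fold and 100 changed 16-fold. Of the genes changed 16-fold, edgeR recovered 71% at 18h, 58% at 20h, 62% at 22h, 3% at 24h and 100% in mESC. DESeq2 1.42.0, the alternative, recovered 83%, 74%, 75%, 22% and 100% of them, with 66, 62, 49, 275 and 1 false calls in place of 7, 4, 7, 1 and 12. Other alternatives were no filter on low counts, a threshold of 0.01, a minimum absolute log2 fold of 1, leaving out each library, the 8 columns of 24h taken separately, stricter sets of peaks, and scaling of peaks by reads in peaks. The last removes any shift common to all peaks of a table, so it cannot test for one. Peak q values, an input or IgG control and values per ChIP library were not used here.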

Results

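RNA of mouse embryos at 18h, 20h, 22h and 24h was compared between control and LoNA KO at each time, and RNA of 2C-like mESC between control and LoNA KD. LoNA is a long noncoding RNA that localises to the nucleolus, and the series asks how loss of a normal nucleolus acts on two-cell gene expression through nucleophosmin and the Polycomb complex PRC2. The 18h, 20h and 22h comparisons had 3 libraries per group, the 24h comparison 2 per group, and the mESC comparison 2 columns per group, which were as alike as the columns summed at 24h. Total counts ran from 12135448 to 15842665 at 18h, from 12077497 to 15419652 at 20h and from 15920815 to 18286944 at 22h. The mESC libraries had 16906302 to 17674190 counts. The 8 columns of 24h were shallower, with 5852761 to 9244870 counts, and 7198 to 9606 genes had a count there against 17125 to 23957 in the other tables. Mitochondrially encoded transcripts took 12.9% to 19.3% of counts at 24h and 1.48% to 9.84% in the other libraries.

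No gene in the tables carries the name LoNA, so the knockout could not be read off under that name. The transcript with the strongest loss was Gm17382 (ENSMUSG00000078838), a lincRNA on the minus strand of chromosome 17 from 26860287 to 26886175, which was named after its values were seen because it was the only gene past the edgeR threshold at each of 18h, 20h and 22h. At 18h it measured 406.9 ± 334.7 CPM (SD, n = 3) in control and 0.0508 ± 0.0465 CPM (SD, n = 3) in KO embryos. The 3 control libraries held 2291, 4186 and 12333 of its counts, and the KO libraries 1, 0 and 1. At 20h the means were 64.7 ± 26.3 and 0.111 ± 0.0761 CPM, and at 22h 58.7 ± 26.1 and 0.0769 ± 0.0667 CPM (SD, n = 3 each). Its log2 change was -12.77 at 18h, -9.08 at 20h and -9.45 at 22h, with edgeR adjusted p of 0.000733, 0.000314 and 0.000687. Across these times the KO libraries held at most 3 counts of it in 9 of 9 cases, and the lowest control count was 507. Gm17382 is not among the genes of the 24h table. In mESC the counts were 402 and 382 in control and 0 and 1 in KD, a log2 change of -9.26 (adjusted p 1.72e-16), but the authors' deposited table gives this gene a mean of 0.257 where these counts give 191.1, so its mESC level is not settled.

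**Figure D1:**
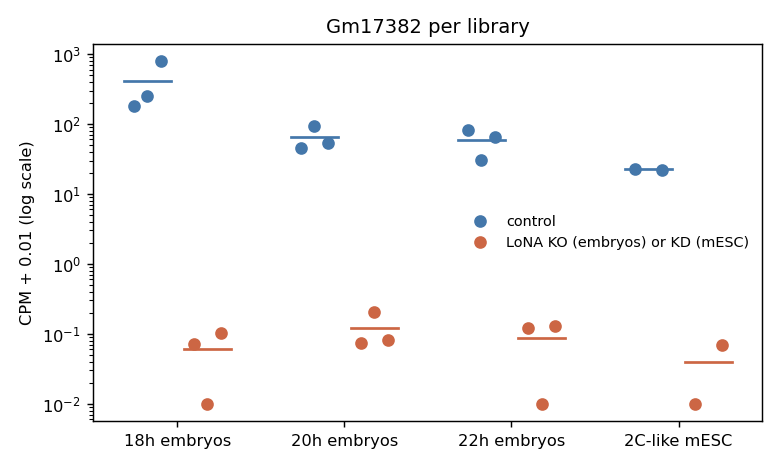
Normalised counts of Gm17382 per library in CPM (log axis, 0.01 added), with points for libraries and a line for the group mean, in embryos at 18h, 20h and 22h and in 2C-like mESC. All 9 KO embryo libraries lie at least a factor of 100 below every control library of their time, and the mESC counts differ from the authors' deposited mean.

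The 18h comparison asks what LoNA loss changed at the first of the sampled times. Beside Gm17382, no gene passed the edgeR threshold at 18h. The largest rises that came near it were Gm15446 (ENSMUSG00000090015, chromosome 5), at 2.53 ± 1.67 CPM in control and 134.5 ± 107.8 CPM in KO, and 1700025G04Rik (ENSMUSG00000032666, chromosome 1), at 3.09 ± 0.75 and 34.1 ± 6.41 CPM (SD, n = 3), each with an adjusted p of 0.0567. Both were chosen after their values were seen. Npm1, which encodes nucleophosmin, a nucleolar histone chaperone, measured 1339 ± 188 CPM in control and 2489 ± 149 CPM in KO embryos (SD, n = 3). The 3 KO libraries were all above the 3 controls, with an adjusted p of 0.744. Ncl, which encodes nucleolin, measured 219.6 ± 36.8 and 307.8 ± 126.1 CPM, and Fbl, the nucleolar methyltransferase fibrillarin, 6.26 ± 2.36 and 6.99 ± 5.91 CPM. Ezh2, the catalytic subunit of PRC2, measured 330.5 ± 29.3 and 546.9 ± 217.7 CPM, and Ep300, which encodes p300, 19.7 ± 6.35 and 26.2 ± 5.96 CPM, with adjusted p of 0.967 and 0.9999.

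Two-cell genes, transcribed at the start of zygotic genome activation, had a positive log2 change for 31 of 41 tested members at 18h, with a median of 0.50 and a camera adjusted p of 0.00172 (adjusted p = 0.84 with an estimated correlation). No member passed over all genes or adjusted over the list alone. Their summed level was 2485 ± 742 CPM in control and 3353 ± 1501 CPM in KO embryos (SD, n = 3), and KO library 1 stood apart at 5080 CPM, while KO libraries 2 and 3 had 2362 and 2617 CPM, within the control range of 1641 to 3033 CPM. Zscan4d, a telomere-associated gene of the two-cell stage, measured 163.3 ± 88.3 and 179.9 ± 113.9 CPM, Zfp352 160.2 ± 73.6 and 96.4 ± 18.0 CPM, and Duxf3, an activator of two-cell genes, 3.58 ± 1.72 and 10.7 ± 6.36 CPM. Cytosolic ribosomal proteins were positive for 76 of 86 members (median 0.55, adjusted p 5.04e-06), mitochondrially encoded transcripts for 15 of 16 (median 0.92, adjusted p 7.85e-05) and replication-dependent histone genes for 22 of 24 (median 1.39, adjusted p 2.59e-06). Each of these also had an adjusted p = 0.84 with an estimated correlation. Hist1h3f was the 1 histone gene higher when adjusted over the list alone, at 9.15 ± 1.87 and 37.1 ± 21.9 CPM, and Obox2 the 1 Obox homeobox gene, at 775 ± 138 and 2178 ± 1339 CPM, where the list as a whole had an adjusted p of 0.354. The mitochondrial share of KO library 2 at 18h was 9.84%, against 2.86% to 5.71% in the other libraries of that time.

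The test at 18h found 0 genes higher and 1 lower of 15416 by edgeR, with 793 genes at an unadjusted p under 0.05. DESeq2 called 34 higher and 64 lower. Groups did not overlap for 1978 genes (12.8%), where chance gives 10%. Biological variation between libraries was wide, with a coefficient of 70.7%, and the simulation recovered 30% of genes changed 4-fold.

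At 20h, which asks the same of embryos 2 h later, Gm17382 fell and the pseudogene AC167192.3 (ENSMUSG00000114550, chromosome 13 from 66281136 to 66284067) rose. AC167192.3 measured 0.151 ± 0.0735 CPM in control and 17.2 ± 6.42 CPM in KO (SD, n = 3), a log2 change of 6.77 with an adjusted p of 0.0476, and it was named after its values were seen. It did not pass at a threshold of 0.01 or after leaving out any of the 6 libraries, and at 22h its log2 change was 1.44 with an adjusted p of 1. Gm15446 again stood apart, at 1.33 ± 1.22 and 38.1 ± 7.03 CPM, with an adjusted p of 0.111. Npm1 measured 2009 ± 191 and 2164 ± 189 CPM, Ncl 226 ± 102 and 301.6 ± 141 CPM, Fbl 10.8 ± 10.5 and 10.3 ± 5.45 CPM, Ezh2 324.5 ± 32.9 and 388.2 ± 10.1 CPM, and Ep300 7.003 ± 2.96 and 22.5 ± 15.99 CPM (SD, n = 3), all with an adjusted p of 0.998. Zscan4d measured 32.8 ± 19.7 and 33.6 ± 28.7 CPM, Zfp352 40.8 ± 23.9 and 25.8 ± 24.1 CPM, and Duxf3 5.18 ± 6.48 and 1.80 ± 1.56 CPM.

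Two-cell genes leaned the other way at 20h, negative for 23 of 36 members with a median log2 change of -0.75 and an adjusted p of 0.0385 (adjusted p = 0.905 with an estimated correlation). Their summed level, 2007 ± 328 CPM in control and 2031 ± 465 CPM in KO, differed in sign from that median. Cytosolic ribosomal proteins were positive for 61 of 86 members (median 0.30, adjusted p 0.00165) and mitochondrially encoded transcripts for 13 of 16 (median 0.42, adjusted p 0.00387), both with an adjusted p = 0.905 with an estimated correlation. No member of these lists passed over all genes or adjusted over the list alone. By edgeR 1 gene was higher and 1 lower of 14524, with 532 at an unadjusted p under 0.05, and DESeq2 called 11 higher and 21 lower. Groups did not overlap for 1433 genes (9.87%).

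At 22h Gm17382 was again the only gene past the edgeR threshold. Npm1 measured 1125 ± 318 CPM in control and 1001 ± 105 CPM in KO, Ncl 345.3 ± 41.2 and 314.3 ± 77.2 CPM, Fbl 3.22 ± 1.13 and 2.79 ± 1.18 CPM, Ezh2 300.3 ± 118 and 286.4 ± 47.9 CPM, and Ep300 12.02 ± 10.7 and 14.2 ± 3.86 CPM (SD, n = 3), all with an adjusted p of 1. Two-cell genes were positive for 28 of 34 members, with a median log2 change of 0.94 and an adjusted p of 0.0249 (adjusted p = 0.992 with an estimated correlation), and summed to 1495 ± 133 CPM in control and 1734 ± 131 CPM in KO. Among them Zscan4d measured 21.0 ± 21.4 and 42.1 ± 26.0 CPM, Zscan4a 1.51 ± 1.34 and 11.99 ± 11.5 CPM, Zfp352 22.4 ± 15.0 and 36.0 ± 18.0 CPM, and Duxf3 4.90 ± 4.24 and 9.94 ± 9.26 CPM. No two-cell gene passed over all genes or adjusted over the list alone. Tbx15, a T-box regulator of mesenchyme, was the 1 developmental regulator higher when adjusted over the list alone, at 0.0198 ± 0.0343 and 2.22 ± 1.85 CPM, with 1 as its adjusted p over all genes.

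Of 15251 genes at 22h, 0 were higher and 1 lower by edgeR, with 481 at an unadjusted p under 0.05. DESeq2 called 3 higher and 1 lower, and groups did not overlap for 1408 genes (9.23%). Gm15446, high in KO at the earlier times, measured 50.7 ± 85.8 CPM in control and 145.8 ± 37.6 CPM in KO, since 1 control library also held it at a high level. Without control library 3 the count of genes higher at 22h was 1.

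The 24h comparison asks about embryos at the time of the chromatin profiles, and no gene passed the edgeR threshold in it. Gata3, a regulator of trophectoderm, measured 79.2 ± 3.25 CPM in control and 0.0353 ± 0.05 CPM in KO (SD, n = 2), a log2 change of -10.86 with an adjusted p of 0.827. Krt18, an epithelial keratin, measured 23.9 ± 3.31 CPM in control and had no counts in KO. Obox2 measured 1376 ± 71.6 and 2970 ± 646 CPM, Oosp1, an oocyte-secreted protein gene, 2462 ± 908 and 5832 ± 1452 CPM, and Npm1 933.6 ± 222 and 1115 ± 359 CPM. Ncl measured 10.9 ± 9.24 and 7.31 ± 10.3 CPM, Ezh2 83.6 ± 62.5 and 100.9 ± 17.6 CPM, and Ep300 15.7 ± 5.78 and 4.804 ± 6.79 CPM, while Fbl had 0.031 ± 0.0438 and 4.78 ± 6.66 CPM and was too low to be tested. Two-cell genes were negative for 21 of 29 members (median -1.35, adjusted p 0.0194, adjusted p = 0.875 with an estimated correlation), among them Zscan4d at 202.9 ± 219 and 79.5 ± 86.8 CPM, and Zfp352 measured 17.5 ± 24.6 and 22.4 ± 31.6 CPM. The summed two-cell level was 2512 ± 1948 CPM in control and 1401 ± 730 CPM in KO (SD, n = 2), from control libraries at 3889 and 1134 CPM and KO libraries at 885.2 and 1917 CPM, so its direction rests on 1 control library.

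Developmental regulators were negative for 5 of 6 tested members at 24h (adjusted p 0.00296), with Gata3, Hoxc10, Neurog2 and Pax6 at or near no counts in KO, and trophectoderm markers for 4 of 6 (adjusted p 0.0194). Both lists also had an adjusted p = 0.875 with an estimated correlation, and no member passed adjusted over the list alone. Blood cell markers, which had too few tested members at the other times, were positive for 4 of 4 at 24h with an adjusted p of 0.792. By edgeR 0 of 7425 genes were higher and 0 lower, with 383 at an unadjusted p under 0.05, and the coefficient of variation was 158%. DESeq2 called 554 higher and 851 lower, in a design where it made 275 false calls on simulated data. Groups did not overlap for 2474 genes (33.3%), and chance gives 33.3% for 2 against 2. Mybbp1a and Cdkn1a, which had counts in KO and almost none in control, are among the genes whose counts differ from the authors' deposited mean.

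The 8 columns at 24h formed 4 pairs. Within a pair the columns correlated at 0.995 to 0.998 across genes, and between pairs at 0.572 to 0.632, whether or not the pairs were of the same group. The difference within a pair, as chi-square per degree of freedom, was 3.19 to 9.49, against 252 to 373 for other pairs of columns at 24h and 40.3 to 161 for libraries of one group at the earlier times. With the columns taken as 8 separate libraries, a setting chosen after the data were seen, edgeR called 346 genes higher and 477 lower, and DESeq2 1485 higher and 2115 lower.

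**Figure D2:**
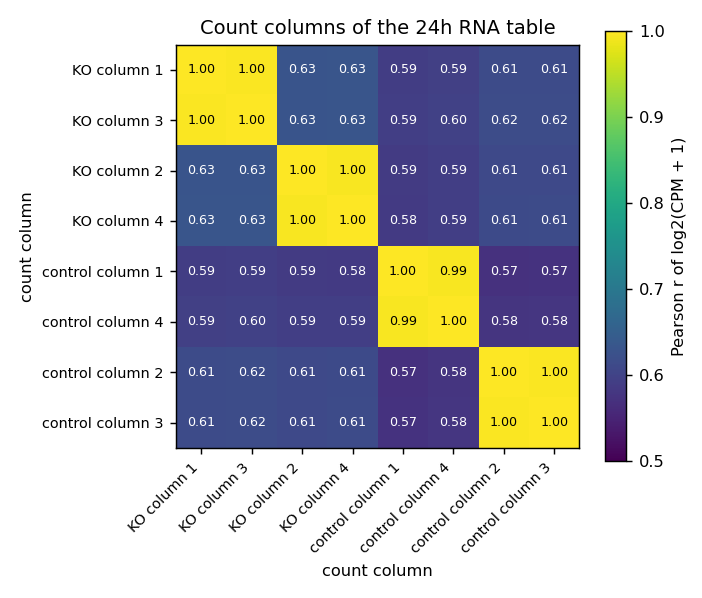
Pearson correlation of log2(CPM + 1) across genes for the 8 count columns of 24h embryos, ordered by pair. Correlations within the 4 pairs were 0.995 to 0.998, and all others lay between 0.572 and 0.632.

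**Figure D3:**
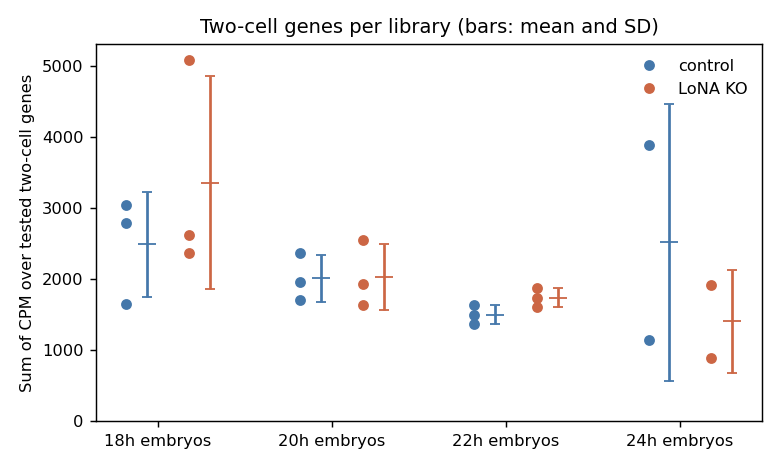
Summed CPM of the tested two-cell genes in each library of control and LoNA KO embryos (points), with the group mean and SD beside them. The groups overlap at each of the 4 times.

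Whether the KO effect differed between times was tested for 12441 genes in the 22 embryo libraries, and 1739 passed by edgeR, with 3723 at an unadjusted p under 0.05. With genotype labels permuted within each time, 24 of 51 labelings, the real one included, gave as many, and the highest other gave 1931. Without the 24h libraries 0 of 18992 genes passed. Across genes, which are not independent replicates, the log2 changes at 18h and 20h correlated at a Spearman rho of 0.131. The permutation test used differences of mean log2 CPM instead, with a rho of 0.12 (exact one-sided permutation p 0.075, 0.638 after adjustment over 10 pairs). The rho of log2 changes was -0.0529 for 18h and 22h, -0.0334 for 20h and 22h, and between -0.0103 and 0.0268 for all pairs with 24h or mESC. Of the 12999 genes tested at 18h, 20h and 22h, 0 were higher without overlap at all 3 times and 4 were lower, namely Gm17382, Aatf, 9830004L10Rik and Gm7426, where chance gives 1.6 in each direction. Aatf, which takes part in ribosomal RNA processing, had log2 changes of -1.50, -1.20 and -0.50.

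In 2C-like mESC, where the question is what LoNA KD changes in cultured cells labelled as two-cell-like, most tested genes passed. The columns of each group correlated at 0.998 (chi-square per degree of freedom 1.99 in control and 3.08 in KD), so the rule that summed columns at 24h would leave 1 library per group here and no test. The calls, SD and p in mESC describe the difference between columns this alike, and say nothing of the spread between separate cultures. Among the largest rises were genes of autonomic neurons and of chromaffin cells of the adrenal medulla, a theme picked out after the data were seen. Chgb, which encodes chromogranin B of secretory granules, measured 0.143 ± 0.122 CPM in control and 523.6 ± 32.6 CPM in KD (SD, n = 2), a log2 change of 11.76, and Scg2, a granin of the same granules, 0.143 ± 0.0406 and 184.1 ± 1.64 CPM. Dbh, the enzyme that makes noradrenaline, had no counts in control and 23.2 ± 2.61 CPM in KD, at least 270-fold higher. Vgf, a neuropeptide precursor, rose from 2.35 ± 0.0806 to 918.2 ± 42.0 CPM, Ret, a receptor tyrosine kinase of neural crest cells, from 3.41 ± 0.527 to 571.4 ± 1.97 CPM, and Prph, a neuronal intermediate filament, from 26.97 ± 0.98 to 755 ± 34.7 CPM.

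Other genes with the largest rises in mESC were Rhox2f and Rhox2d, reproductive homeobox genes of the X chromosome, at least 272-fold and 306-fold higher over a control without counts. Gh, growth hormone, and Icam2, a cell adhesion gene, were at least 245-fold and 256-fold higher. Fam163a rose from 0.0287 ± 0.0406 to 45.6 ± 3.84 CPM and Rab3c, a GTPase of vesicle release, from 0.0861 ± 0.122 to 94.9 ± 5.68 CPM. Among developmental regulators 9 of 26 rose and 13 fell (14 fell adjusted over the list alone), with Gata2 rising from 6.74 ± 0.851 to 147.3 ± 3.58 CPM, Sox9 from 1.15 ± 0.487 to 54.7 ± 1.57 CPM, Gata4 from 7.72 ± 0.445 to 58.9 ± 1.04 CPM and Nkx2-5 from 1.03 ± 0.0809 to 27.9 ± 0.0167 CPM. As a list they had an adjusted p of 0.538.

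Pluripotency genes fell, with 21 of 23 lower and 0 higher, also when adjusted over the list alone, and a median log2 change of -1.01 (adjusted p 3.33e-07, adjusted p = 0.297 with an estimated correlation). Tet1, which oxidises methylated cytosine, fell from 895.5 ± 19.8 to 282.5 ± 21.6 CPM, Tfcp2l1, a transcription factor of naive pluripotency, from 314.1 ± 7.94 to 108.3 ± 7.28 CPM, and Esrrb, a nuclear receptor of the same network, from 681.9 ± 2.42 to 295.6 ± 0.961 CPM (SD, n = 2). Two-cell genes fell too, with 13 of 15 lower (14 adjusted over the list alone), a median of -1.08 and an adjusted p of 0.000556 (adjusted p = 0.297 with an estimated correlation). Markers of granulosa cells (median -1.04) and of fibroblasts (median -1.14) fell by a like amount, so a fall of this size was not particular to two-cell genes. The summed two-cell level was 66.0 ± 1.84 CPM in control and 36.0 ± 1.73 CPM in KD. In control embryos it was 1495 to 2512 CPM, over 29 to 41 tested members against 15 in mESC. The two-cell-like state is thus given by the label and not shown by the level of these genes. Zscan4d fell from 2.58 ± 0.811 to 1.06 ± 0.0165 CPM, with an adjusted p of 0.00138, while Zfp352 and Duxf3 were too low to be tested. Trophectoderm markers were lower for 12 of 14 and higher for 1 (median -1.03, adjusted p 0.00376), and cell cycle genes lower for 20 of 31 and higher for 4 (median -0.31, adjusted p 0.0114), each with an adjusted p = 0.297 with an estimated correlation.

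Nucleolar genes went both ways in mESC. Npm1 fell from 2374 ± 22.9 to 2242 ± 7.72 CPM (log2 change -0.08, adjusted p 0.0385), Ncl from 1660 ± 26.3 to 1548 ± 60.9 CPM (log2 change -0.10, adjusted p 0.021), and Fbl rose from 249.4 ± 10.7 to 272.2 ± 12.7 CPM (log2 change 0.13, adjusted p 0.012). Ribosome biogenesis genes were higher for 16 of 45 and lower for 17, with an adjusted p of 0.538. PRC2 subunits were lower for 8 of 12 and higher for 1 (median -0.52, adjusted p 0.028, adjusted p = 0.35 with an estimated correlation), and Ezh2 fell from 225.1 ± 7.07 to 176.5 ± 4.10 CPM, Suz12 from 256.8 ± 2.13 to 160.8 ± 0.00497 CPM and Jarid2 from 427.8 ± 8.74 to 265.9 ± 1.62 CPM. Among histone acetylation enzymes 5 of 17 rose and 8 fell (9 adjusted over the list alone), with an adjusted p of 0.482, and Ep300 fell from 163.3 ± 0.442 to 125.5 ± 2.51 CPM. Cytosolic ribosomal proteins were higher for 57 of 88 and lower for 14 (median 0.21, adjusted p 0.027, adjusted p = 0.717 with an estimated correlation). Mitochondrially encoded transcripts rose in 14 of 14 cases (median 1.13, adjusted p 0.000556, adjusted p = 0.305 with an estimated correlation), with mt-Cytb going from 1223 ± 61.8 to 4541 ± 152 CPM. The mitochondrial share was 1.48% and 1.53% of counts in control and 2.26% and 2.24% in KD.

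**Figure D4:**
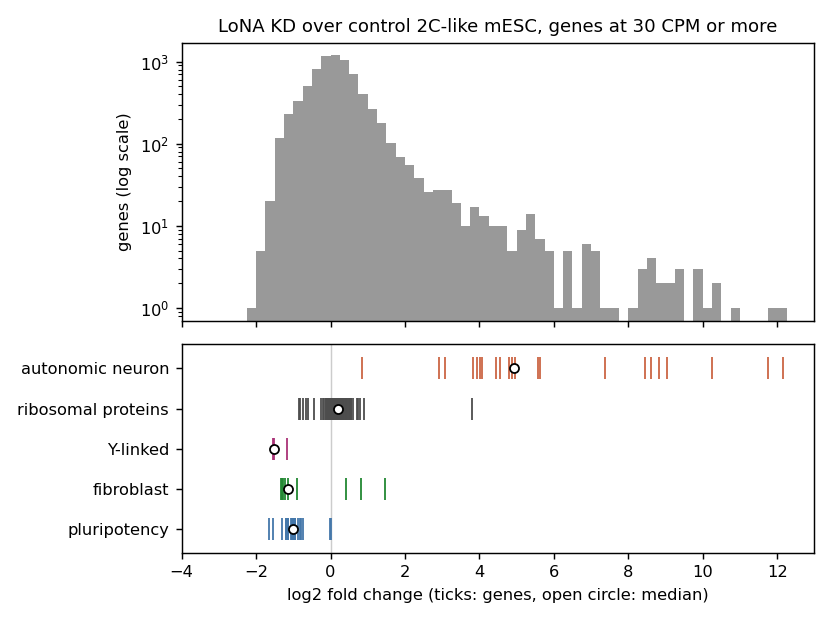
Histogram of log2 fold changes, LoNA KD over control 2C-like mESC, for genes at 30 CPM or more in either group (count on a log axis), and below it each gene of 5 lists as a tick with the list median as an open circle. Of 7461 genes, 1 was 4-fold or more lower and 336 were 4-fold or more higher.

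The remaining lists of mESC included markers of other cell types. Cumulus and granulosa cell markers were lower for 9 of 12 and higher for 0 (median -1.04, adjusted p 0.00457, adjusted p = 0.384 with an estimated correlation). Fibroblast markers were lower for 10 of 14 (11 adjusted over the list alone) and higher for 3 (median -1.14, adjusted p 0.0109, adjusted p = 0.297 with an estimated correlation). Major genome activation genes were higher for 7 of 22 and lower for 14 (adjusted p 0.0967), p53 and stress response genes higher for 7 of 22 and lower for 12 (adjusted p 0.493), maternal oocyte genes higher for 2 of 10 and lower for 5 (adjusted p 0.538), and replication-dependent histone genes higher for 4 of 21 (3 adjusted over the list alone) and lower for 0 (adjusted p 0.538). In embryos the maternal oocyte list had an adjusted p of 0.963 at 18h, and sperm and testis markers, with 3 tested members, 0.565.

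Gm17382 aside, and among named genes at 10 CPM or more that are neither predicted genes nor pseudogenes, the largest falls in mESC were smaller than the largest rises. Zyg11a, a substrate receptor of a ubiquitin ligase, fell from 27.7 ± 1.30 to 5.84 ± 0.0905 CPM (log2 change -2.24), Gdap10 from 26.7 ± 0.412 to 6.00 ± 1.41 CPM and Prrg4 from 22.2 ± 0.938 to 5.13 ± 0.33 CPM. Notch1, a receptor of cell fate decisions, fell from 78.0 ± 1.04 to 24.1 ± 1.17 CPM, and Lrp2, an endocytic receptor, from 40.1 ± 1.47 to 11.8 ± 0.433 CPM. The further falls of this kind were Cdyl2, Diaph2, Erdr1, Itpripl2 and Sorl1, with log2 changes from -1.78 to -1.67.

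By edgeR 6378 of 16406 genes were higher and 5799 lower in KD mESC, and 12436 had an unadjusted p under 0.05. DESeq2 called 5563 and 3950. With a minimum fold of 2 the counts were 2500 and 2249. Groups did not overlap for 14205 genes (86.6%), where chance gives 33.3%. The coefficient of variation between libraries was 3.39%, far below the 55.5% to 158% of the embryo tables, and the p describes this small spread alone. If the columns of each group are repeats of 1 library, the comparison has no replicates.

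In 24h embryos the deposited H3K27me3 table, a mark laid down by PRC2, holds 11638 peaks with a median width of 706 bp, and the H3K4me3 table, a mark of active and poised promoters, 48658 peaks with a median width of 827 bp. Each condition has 1 column of values, so no test between conditions was made, and all RPM values and log2 ratios of single peaks are those of the authors' deposited tables. Total reads were 47253912 in control and 50153338 in KO for H3K27me3, and 66601350 and 49648616 for H3K4me3. H3K27me3 peaks held 6.77% of control reads and 6.95% of KO reads, and H3K4me3 peaks 42.2% and 39.3%.

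Developmental regulators stood out in H3K27me3, with a promoter peak at 28 of 41 genes (68.3%) against 3561 of 20021 protein-coding genes (17.8%), an odds ratio of 10 (Fisher's exact test, two-sided, adjusted p 5.43e-11 over 76 tests). By the authors' deposited table the peak of Isl1 on chromosome 13 from 116309349 to 116309791 had 2.48 RPM in control and 3.51 RPM in KO, a log2 ratio of 0.50 (95% interval 0.16 to 0.85). The peak of Gata3 on chromosome 2 from 9889013 to 9889690 had 7.34 and 9.63 RPM, a log2 ratio of 0.39 (0.19 to 0.59). The median log2 ratio over the 32 promoter peaks of this list was 0.08, and 17.9% of random sets of promoter peaks of like read depth had a lower median. Trophectoderm markers held a peak at 9 of 16 promoters (adjusted p 0.00241), with a median log2 ratio of 0.31 at percentile 99 of random sets. Two-cell genes held an H3K27me3 peak at 4 of 40 promoters, and a peak of Duxf3 on chromosome 10 from 58231176 to 58232820 had 29.1 RPM in control and 31.8 RPM in KO (log2 ratio 0.13, 0.02 to 0.23), while a second from 58233243 to 58233978 had 13.2 and 11.8 RPM (log2 ratio -0.16, -0.33 to 0.00268). Over all H3K27me3 peaks the median log2 ratio was 0.0599, which became 0.022 when scaled by reads in peaks, and 3 peaks were 2-fold or more higher and 26 lower. The highest single peak by the authors' ratio lay at the start of Terb1 (log2 ratio 1.12). The lowest lay 9134 bp from the nearest protein-coding start, that of Zfp945 (log2 ratio -2.44).

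H3K4me3 marked promoters of 14508 of 20021 genes (72.5%), among them 45 of 45 ribosome biogenesis genes, 84 of 85 cytosolic ribosomal protein genes and 60 of 60 replication-dependent histone genes, and 4 of 40 two-cell genes (odds ratio 0.042, Fisher's exact test, adjusted p 1.27e-14). Many two-cell genes belong to the same families, such as Zscan4a and Zscan4d, which the test counts as independent genes. Whether reads could be placed at such related genes was not tested. The 48 promoter peaks of histone genes had a median log2 ratio of -0.50, below the median of all 10000 random sets of promoter peaks of like read depth. The 24 of the p53 and stress response list had a median of -0.26, also below all random sets. With 1 library per condition, a difference between the libraries at such peaks cannot be told from a KO effect. Over all H3K4me3 peaks the median was -0.127, or -0.021 when scaled by reads in peaks. Peaks at 2-fold or more numbered 5 higher and 33 lower. The highest (log2 ratio 1.35) overlapped AC166358.2 and lay 1156631 bp from the nearest protein-coding start, that of Gm10330. The lowest (log2 ratio -1.51) overlapped Ppp1r9a, with the nearest protein-coding start, that of Pon1, 63823 bp away. The H3K4me3 peaks at Duxf3 on chromosome 10 had 3.47 and 6.00 RPM between 58233342 and 58233887 (log2 ratio 0.79, 0.54 to 1.05), and 14.9 and 17.3 RPM in the larger one between 58231244 and 58232874 (log2 ratio 0.22, 0.08 to 0.35).

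AcNPM1 was compared between KO and control and between KO with p300 inhibitor and KO, to ask where acetylated nucleophosmin sits and whether p300 activity is needed for it. The first table holds 9602 peaks and the second 11745, with 32077472 total reads in control, 60297174 in KO and 37816980 with inhibitor. Developmental regulators had an AcNPM1 promoter peak at 21 of 41 genes in the first table (adjusted p 1.62e-06) and at 24 of 41 in the second (adjusted p 1.54e-07). By the authors' deposited table the peak of Neurog2 on chromosome 3 from 127633220 to 127634811 had 12.9 RPM in control and 19.5 RPM in KO (log2 ratio 0.60, 0.44 to 0.76), and that of Pax6 on chromosome 2 from 105666477 to 105666985 had 5.36 and 8.23 RPM (log2 ratio 0.62, 0.36 to 0.88). These were the highest of the list, whose 25 promoter peaks had a median log2 ratio of 0.16, at percentile 11.1 of random sets of promoter peaks of like read depth. The peak of Duxf3 on chromosome 10 from 58231200 to 58232781 had 22.0 RPM in control, 21.9 RPM in KO and 22.9 RPM with inhibitor, and a second from 58233309 to 58233997 had 8.60 RPM in control and 9.20 RPM in KO. Pluripotency, ribosomal protein and histone genes had 0 promoter peaks in the first table.

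The median log2 ratio of AcNPM1 peaks, KO over control, was 0.143, and 6568 of 9602 peaks (68.4%) were above 0. Scaled by reads in peaks, a setting chosen after the data were seen, it was -0.0075. With inhibitor over KO it was -0.0831, or 0.0025 when scaled by reads in peaks. That scaling divides by the reads of these same peaks, which removes any shift common to them and brings the median near 0. The scaled signs therefore decide nothing, and with 1 column per condition the direction over all peaks stays open. Peaks with 2-fold or more numbered 38 higher and 21 lower in KO, and 15 higher and 47 lower with inhibitor. The lowest with inhibitor lay 4541 bp from the start of Tcstv3, a two-cell gene, on chromosome 13 from 120321419 to 120321637. It had 23.7 RPM in KO and 4.71 RPM with inhibitor (log2 ratio -2.33, -2.57 to -2.11). The highest with inhibitor overlapped Acacb, 26571 bp from its start (log2 ratio 1.79). In KO over control the highest (log2 ratio 1.78) lay 38897 bp from the nearest protein-coding start, that of Dpy19l1. The lowest (log2 ratio -1.60) lay 74860 bp from the start of a gene whose name is given in date form. A peak that overlapped Plcb4, 63442 bp from the nearest protein-coding start (Lamp5), was among the highest in KO, at 1.19 and 3.95 RPM. The same region was among the lowest with inhibitor, at 3.32 RPM in KO and 1.03 RPM with inhibitor. Both tables share the KO reads, and over 7960 overlapping peaks their log2 ratios correlated at a rho of -0.458. In 100 simulations of the shared column rho was -0.343 on average and -0.373 at the lowest. Errors of the KO column beyond those simulated enter the ratios with opposite sign and would lower rho further. The gap therefore cannot tell such errors from an effect of the inhibitor.

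AcNPM1 peaks of the first table overlapped H3K27me3 peaks in 78.2% of cases, 104 times the shuffled mean, and H3K4me3 peaks in 74.5%, 22.6 times the shuffled mean. Of H3K27me3 peaks 63.8% overlapped AcNPM1 and 71.0% overlapped H3K4me3, and 82.9% of the first AcNPM1 list overlapped the second. Each overlap had a one-sided permutation p of 0.001, the smallest that 1000 shuffles can give. The shuffles ignored where promoters lie, and 32.2% to 36.2% of the peaks of each list lay at promoters. This p therefore cannot tell a link between 2 profiles from a shared preference for promoters. Over overlapping peaks the control signals of AcNPM1 and H3K27me3 correlated at a rho of 0.882, or 0.901 per base pair, and those of AcNPM1 and H3K4me3 at 0.364. An AcNPM1 promoter peak was held by 79.3% of 3418 genes with both marks (95% interval 77.9% to 80.7%), by 46.2% of 143 with H3K27me3 only (37.8% to 54.7%), by 3.18% of 11090 with H3K4me3 only (2.86% to 3.53%) and by 0.615% of 5370 with neither (0.423% to 0.862%).

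**Figure D5:**
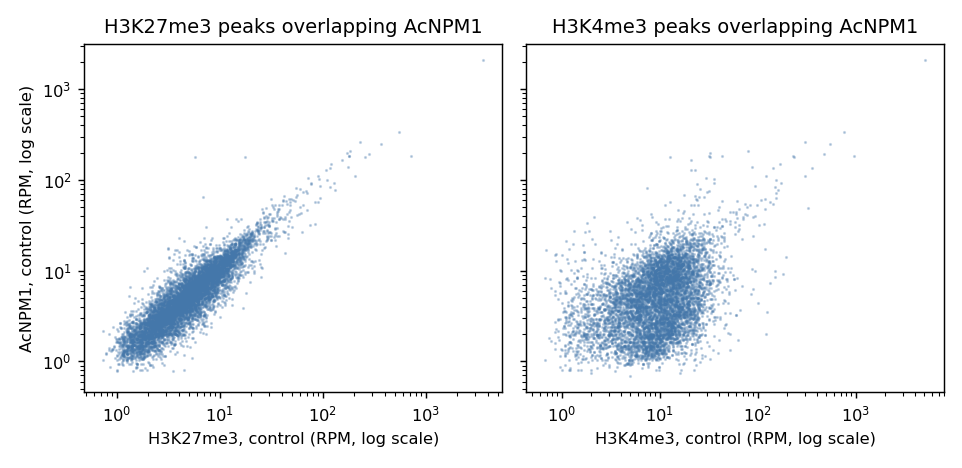
Signal in RPM (log axes) of AcNPM1 against H3K27me3 over H3K27me3 peaks that overlap an AcNPM1 peak, and against H3K4me3 over H3K4me3 peaks that do, in control 24h embryos, with each point a peak. The Spearman rho is 0.882 for H3K27me3 and 0.364 for H3K4me3.

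Set against RNA, genes whose promoter had H3K4me3 only were expressed enough to be tested at 22h in 79.5% of cases, with a median of 18.8 CPM in control embryos. Those with both marks were tested in 51.5% of cases (median 6.81 CPM), those with H3K27me3 only in 35.7% (3.34 CPM) and those with neither in 35.1% (4.92 CPM). At 24h, the time of the chromatin profiles, the shares tested were 41.6%, 20.4%, 12.6% and 16%, and the medians of tested genes did not follow the same order, at 25.4, 20.6, 14.2 and 24.8 CPM. At 24h edgeR called no gene from the 4 libraries, so promoter peaks could be set only against calls from the 8 columns taken separately. Of the 387 genes lower by those calls and in the annotation, 57 had an H3K27me3 promoter peak (14.7%, against 11.3% of other genes), with an adjusted p of 0.181 by Fisher's exact test over 8 tests, and none of the 8 tests passed.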

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

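The interaction test and the gene lists fixed before the data were examined, the pluripotency list among them, were planned. The other tests in this part were chosen only after the results they concern had been seen. The KO effect of 1739 genes differed between 18h, 20h, 22h and 24h by the interaction test, which is what marked it for a closer look. With genotype labels permuted within each time, 24 of 51 labelings gave as many, so the spread between libraries, above all at 24h, may account for this count. For single times, 10 splits of the 6 libraries are too few for a share under 0.05. Counting the real grouping itself, 2 of 10 splits gave as many calls as it did at 18h (1 call, highest other 2), 2 of 10 at 20h (2 calls, highest other 5) and 2 of 10 at 22h (1 call, highest other 1).

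Autonomic neuron and chromaffin cell genes, a list written after the data were seen, were higher in the KD mESC libraries for 26 of 31 members and lower for 3 (4 adjusted over the list alone), from a sum of 408.2 to 6122 CPM (camera p 8.70e-09, p = 0.0529 with an estimated correlation). A share of cells of another origin could give this: it lowers only transcripts that those cells lack or hold at a lower level, and by no more than the share allows, and only 0.0134% of genes at 30 CPM or more, 1 of 7461, were 4-fold or more lower, while 4.50% were 4-fold or more higher. That limit of 30 CPM was chosen after the data were seen, and at 10 CPM or more, with Zyg11a, Gdap10 and Prrg4 among them, 12 of 10641 genes were 4-fold or more lower and 623 higher. Chgb, Vgf and Ret were at 523.6, 918.2 and 571.4 CPM in KD, and control cells held 6 of the 31 genes at 10 CPM or more. Y-linked genes had a median log2 change of -1.29 (5 of 6 lower, camera p 0.00566, p = 0.253 with an estimated correlation). That list was also written after the data were seen, and lists not tied to a chromosome fell by a like amount, as given below. The Y-linked fall therefore cannot decide on a change of state in cells that kept their chromosomes. The ratio of library totals was 1.04, but CPM values are already scaled for library size, so this ratio bears on neither explanation. The falls of pluripotency genes, with a median log2 change of -1.01 and an interquartile range of 0.286, could come from such a share or from LoNA KD, and both stay open. The lowest of 21, Tet1, differed from Nanog by -0.652 (standard error 0.0602). Tet1 is the extreme of the list, however, and that error rests on near-identical columns. Falls of like size were seen in two-cell genes (median -1.08) and in trophectoderm (-1.03), granulosa (-1.04) and fibroblast markers (-1.14). Lists such as cell cycle genes (-0.31) and cytosolic ribosomal proteins (0.21) did not show them. Whether these falls come from such a share or from LoNA KD stays open as well.

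At 24h the 8 columns gave 823 calls by edgeR and the 4 summed libraries none. The columns of a pair may be repeats of 1 library, since their difference was at most 9.49 by chi-square per degree of freedom against at least 252 for all other pairs. A LoNA effect larger than the differences between libraries is argued against, because 3 of 3 splits of the 4 libraries into pairs, the real one included, gave at least 823 calls, the others 872 and 1078. Each of these splits enters near-identical columns as separate libraries, so the calls cannot tell genotype from differences between single libraries.

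AcNPM1 signal followed H3K27me3 signal across peaks. Of the promoters highest in H3K4me3 and without H3K27me3 only 2.95% had an AcNPM1 peak, against 46.2% of those with H3K27me3 only. High H3K4me3 alone thus seldom went with an AcNPM1 peak. On preferential cutting of open chromatin this cannot decide. Openness was not measured, and the set leaves out promoters with a peak in the H3K27me3 profile, made with the same kit. The rho was 0.877 without the top 1% of peaks and the sex chromosomes, which decides nothing on a few regions of extreme signal, since ranks move little when 1% is left out. Whether the antibody or a shared background of the profiles could give this was not tested, since no input or IgG control was used here, and binding of AcNPM1 at PRC2 targets remains possible.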

How the results depend on the processing

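For the values that answer a comparison, 111 kept their direction and their side of the threshold or limits, 75 moved and 2 reversed over all alternatives. For named genes, 4227 were the same, 103 stronger and 29 weaker, and single named peaks were not run under any alternative. A gene that passed the threshold in neither setting was counted as the same, even where its sign changed. For embryo genes, of which few passed, this count therefore says little. Apart from the sets of peaks cut by fold and the scaling by reads in peaks, both described below, the cause was not tested for results that moved or reversed. DESeq2 in place of edgeR called 34 higher and 64 lower at 18h, 11 and 21 at 20h, 3 higher at 22h, and 554 and 851 at 24h. Without a filter on low counts edgeR called 44 higher and 28 lower at 18h, 4 and 11 at 20h, 30 and 3 at 22h, and 3 lower at 24h. At a threshold of 0.01, 0 genes were higher at 20h, and with a minimum log2 fold of 1 mESC had 2500 higher and 2249 lower.

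Leaving out each library in turn, genes higher and lower ranged from 0 to 0 and 1 to 1 at 18h, 0 to 0 and 1 to 2 at 20h, 0 to 1 and 1 to 1 at 22h, 0 to 23 and 0 to 16 at 24h, and 5840 to 6147 and 4634 to 5189 in mESC. At 20h the higher call was lost without any of the control or KO libraries 1 to 3, and 2 genes were lower without KO 3. At 22h 1 gene was higher without control 3, and at 24h calls arose without control 1 or 2, and 1 lower call without KO 1. Where a group was left with 1 library, that library was assumed to vary like the others.

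With an estimated correlation camera passed 0 lists at 18h, 0 at 20h, 0 at 22h, 0 at 24h and 0 in mESC, and fry passed 0 lists at 18h, 20h, 22h and 24h but 12 in mESC, against 9 with camera. Among genes above the median level the correlation of effects was 0.297 for 18h with 20h, -0.118 for 18h with 22h, -0.00279 for 20h with 24h and 0.0189 for 22h with 24h.

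Some alternatives were chosen after the data were seen. The 8 columns of 24h taken separately gave 346 higher and 477 lower by edgeR, and 1485 and 2115 by DESeq2. With these calls 90 genes had an H3K27me3 promoter peak, 590 an H3K4me3 peak, 81 an AcNPM1 peak of KO over control and 95 one of inhibitor over KO. Taking only the first or the second column of each pair left the counts within limits. The interaction with 18h, 20h and 22h only passed 0 genes.

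Median log2 ratios of H3K27me3, H3K4me3, AcNPM1 in KO and AcNPM1 with inhibitor were 0.23, -0.27, 0.33 and -0.26 in the top 50% of peaks by the authors' fold. That set is picked by the size of the same ratio, so the larger medians follow from the selection and decide nothing. In the top 50% by summed reads, a setting chosen after the data were seen, the medians were 0.092, -0.13, 0.21 and -0.11. Scaled by reads in peaks, also chosen then, they were 0.022, -0.021, -0.0075 and 0.0025, the last pair reversed. This scaling divides by the reads of the same peaks, so medians near 0 follow from it and decide nothing on direction. In the top 50% by fold and by summed reads, H3K27me3 peaks overlapped H3K4me3 in 30.6% and 68.2%, AcNPM1 of KO over control in 31.3% and 70.6%, and AcNPM1 of inhibitor over KO in 35.5% and 79.3%. H3K4me3 peaks overlapped both AcNPM1 lists in 6.21% and 13.7%, and in 7.34% and 15.9%. The first AcNPM1 list overlapped the second in 46.0% and 93.9%. Both lists of an overlap were cut, so the lower shares by fold can come from the cut itself.

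Column names share numbers between groups, at 24h those of the summed columns, but these did not pair the libraries: correlations of deviations from the group mean for the same number ran from -0.116 to 0.109, and not every library correlated best with its own number. With that number as a replicate block edgeR called 1 gene higher and 1 lower at 18h, 2 and 2 at 20h, 0 and 1 at 22h, 0 and 0 at 24h, and 6506 and 5903 in mESC, and Gm15446 passed at 18h and 20h (adjusted p 0.0155 and 0.00129). A pseudocount and a filter on low values were not run because the tables hold counts, nor was a stricter q because the peak tables hold none, nor were peaks without each library because each condition has 1 column, nor the authors' unadjusted p because the tables hold none. Summing the mESC columns, as at 24h, leaves 1 library per group and no test, so it was not run. Each column of 24h held counts for 7198 to 9606 genes, and genes under the filter were not tested.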

Other observations

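At 18h the Y-linked genes Ddx3y, Eif2s3y and Usp9y had 2.67 ± 2.39, 4.68 ± 5.45 and 6.08 ± 3.41 CPM in control embryos and no counts in KO embryos (SD, n = 3), and Kdm5d had 2.24 and 0.789 CPM. As a list written after the data were seen, 3 of the 4 were lower adjusted over the list alone and none over all genes (camera p 1.92e-08, p = 0.0175 with an estimated correlation). At 20h 2 of 3 tested Y-linked genes were positive (p 0.323). In mESC Ddx3y fell from 59.3 to 20.8 CPM and Xist, which silences 1 X chromosome in female cells, rose from 26.4 ± 3.33 to 221.2 ± 10.9 CPM. Primitive streak and gastrulation genes, also listed after the data were seen, were higher for 2 of 7 and lower for 3 in mESC (camera p 0.372).

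The tests in this part were chosen only after the results had been seen. A hypothesis on Gm17382 is this lincRNA being the deleted transcript, which needs it to be all but absent from every KO library. KO libraries with 3 or fewer of its counts numbered 9 of 9, against at least 507 counts in each control library, but the gene was picked from these same libraries, so the count repeats what prompted the hypothesis and leaves it open. The position of the deletion was not used here.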
